A study of Mus musculus with 12 samples.

How the data were processed

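RNA was measured by sequencing in 12 libraries of whole mouse pancreas, per the labels 1 library for each animal. The mice were C57Bl6 controls, called wild type here, and a congenic Atf3-/- line, called labelled knockout here because the Atf3 counts do not fall in it. Per the labels the animals were 2 to 4 months old and received 4 injections of saline or of cerulein (50 ug/kg each), a cholecystokinin analogue, and the tissue was taken at 4 h. Each of the 4 groups holds 3 libraries from separate animals, as the series' design states, and the libraries are named by the group and the code in their labels (W1, K5 and R3 for wild type with saline, O1, O3 and N3 for wild type with cerulein, S1, K4 and Q1 for labelled knockout with saline, C2, C3 and L4 for labelled knockout with cerulein).

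The deposited values are read counts per Ensembl gene, whole numbers with no normalization, from an Illumina stranded kit for total RNA. The submitters' processing notes name HTSeq, DESeq2 and the mm10 build, without versions or roles. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Each library lists 49585 genes, of which 49326 were matched by identifier to GENCODE M21 on GRCm38 for symbols and coordinates. The totals ran from 18292997 to 32158629 counts per library. No library was left out of the 12-library results.

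Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Tables and figures used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr on the 4 groups (14329 genes), scaled by TMM, and fitted in 1 robust quasi-likelihood model with a mean for each group. The common dispersion, as a biological coefficient of variation, was 0.357. The labels give no batch, day, sex or litter, so the model has no such term. No paired analysis was possible because no replicate code is shared between groups.

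The 5 comparisons were cerulein against saline in wild type, the same in the labelled knockout, labelled knockout against wild type in saline and in cerulein, and the difference of the 2 cerulein responses (an interaction). Each was tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A standard error is the log2 fold change divided by the square root of F. Values per library are CPM (counts scaled to a library total of 1e6) on TMM-scaled library sizes for Atf3 and on plain totals for the single marker genes of a library. The log2 values behind principal components used a prior count of 2. The response size is the median, over genes past the threshold in the cerulein response averaged over both genotypes, of the interaction log2 fold change taken with the sign of the averaged response. The response score places each library on the line between the wild-type saline mean (0) and the wild-type cerulein mean (1) over 5632 genes. These genes passed the threshold between those groups in a fit of the wild-type libraries alone. The score was defined after the values were seen.

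Before the data were examined, 29 gene lists with 467 members were fixed from general knowledge, and all members were found, 2 of them under a newer symbol. Acinar and secretory lists were digestive enzymes and secretory proteins, acinar identity and maturity, and the Reg family. Stress and signalling lists were the integrated stress response, endoplasmic reticulum (ER) chaperones, immediate early genes, cytokines and chemokines, NRF2 targets, heat shock proteins, and actin cytoskeleton and SRF targets. Cell-type lists held markers of neutrophils, macrophages and monocytes, lymphocytes, ducts, islets, fibroblasts, endothelium, adipocytes and erythroid cells. The remaining lists were cholesterol biosynthesis, cell cycle, ribosome biogenesis, fatty acid oxidation, HDAC and chromatin regulators, mitochondrially encoded mRNAs, nuclear noncoding RNAs, replication-dependent histones and sex-linked check genes. Each list was tested per comparison with camera (limma), which compares its members with all other genes, at a preset correlation of 0.01 and again with a correlation estimated for each list, with Benjamini-Hochberg adjustment over the lists. Members were also counted past the threshold over all genes and adjusted over the list alone. Atf3 is in no list. Of the 29 lists 1 is not reported here, nor are some of the named genes, but they stay in the tests and in the counts of lists and genes.

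Named genes followed a rule fixed before the data were examined. It takes Atf3, and for each comparison the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean CPM of at least 1 whose libraries do not overlap between the groups. It skips unnamed gene models. From each list it takes up to 4 members past the threshold with the largest change, or the 2 most abundant members where none passed.

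A fold against a group with no counts is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio has its exact binomial interval at 95%. These intervals and floors cover counting error only.

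Alternatives fixed in advance were the DESeq2 Wald test, DESeq2 size factors with the edgeR test, scaling without the 50 most abundant genes, no filter on low counts, a stricter filter (CPM of at least 1 in at least 3 libraries), a fit of the 2 groups compared alone, limma-voom, and each library of the compared groups left out in turn. Chosen after seeing the data were the fits without C3 for the wild-type and saline comparisons, DESeq2 and limma-voom without C3, the fits without N3 and K4, without N3, K4 and C3, and with only the libraries that hold Y-linked counts. So was the size of the immune, adipocyte, ribosome biogenesis and heat shock lists in the interaction. It is given as the median of the members and as the difference of library means. The latter is the difference of each list's mean log2 CPM per library, with a standard error from the spread within groups. The fit without C3 tested 14733 genes with a coefficient of variation of 0.304.

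The procedure was tested on simulated counts with 200 changed genes. With 12 libraries, at a 4-fold change it recovered 68% of them in the wild-type response and 38.5% in the interaction, and at 8-fold 87.5% and 76.5%. At 2-fold it recovered 0% in both. In the data 4399 genes passed in the wild-type response, so its adjustment over genes is less strict than with 200 changed genes. The recovered shares thus do not apply to that response. Every recovered gene had the right sign, and at most 9 unchanged genes were called in any simulation. A simulated response size of -1 was found as -0.997. A list of 20 genes changed 1.5-fold gave a camera adjusted p of 2.79e-10, and 0 of 28 other lists passed. Each simulated gene was drawn independently, so this does not test the list calls where members vary together.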

Results

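Whole pancreas was sequenced from wild-type C57Bl6 mice and from a congenic line labelled Atf3-/-, 4 h after the start of saline or cerulein injections. The 12 libraries form 4 groups of 3 animals each. Wild-type saline libraries held 18292997 (W1), 20488830 (K5) and 25958479 (R3) counts. Those of wild type with cerulein held 24494819 (O1), 20376507 (O3) and 22286741 (N3). The libraries labelled knockout and saline held 26785935 (S1), 20836916 (K4) and 21305572 (Q1), and those labelled knockout and cerulein 24506120 (C2), 23493549 (C3) and 32158629 (L4). The 10 most abundant genes, led by Ctrb1 or Pnlip, took 53.0% to 57.6% of the counts in the saline libraries and 44.6% to 46.8% in the cerulein libraries other than C3, where they took 53.9%.

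Atf3, the gene targeted in the congenic line (ENSMUSG00000026628, GRCm38 chromosome 1, 191170296 to 191218039, minus strand), encodes a stress-induced transcription factor. Its normalised level in wild type was 3.23, 1.13 and 5.28 CPM in saline and 775, 599 and 394 CPM in cerulein. In the libraries labelled knockout it was 23.1 (S1), 7.44 (K4) and 13.5 CPM (Q1) in saline, and 1375 (C2), 20.7 (C3) and 1636 CPM (L4) in cerulein. Atf3 counts were thus not lower where the label says knockout. In saline all 3 labelled knockout libraries lay above all 3 wild-type libraries, a log2 fold change of 2.18 ± 1.09 (SE, n = 3 per group) that did not pass edgeR's test (adjusted p = 1, unadjusted p = 0.0709). Without C3, which is in neither saline group, it was 2.175 ± 0.549 and edgeR's unadjusted p was 0.00281. It did not pass there either, nor by DESeq2 without C3 (adjusted p = 0.0979). In cerulein the difference was 0.78 ± 1.02 (adjusted p = 0.789), and it was -0.73 by limma-voom. Without C3 it was 1.35 ± 0.55 (adjusted p = 0.974), and 1.40 by limma-voom. Atf3 rose in wild type by 7.51 ± 1.36 on the log2 scale (adjusted p = 0.00918). In the labelled knockout the change was 6.11 ± 1.27 (adjusted p = 0.086), and without C3 it was 6.68 ± 0.66 (adjusted p = 8.84e-05). By DESeq2 with C3 kept the labelled knockout change was 6.07 (adjusted p = 7.74e-06). The labels do not state which part of the gene was deleted, and the counts are for the whole gene.

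**Figure D1:**
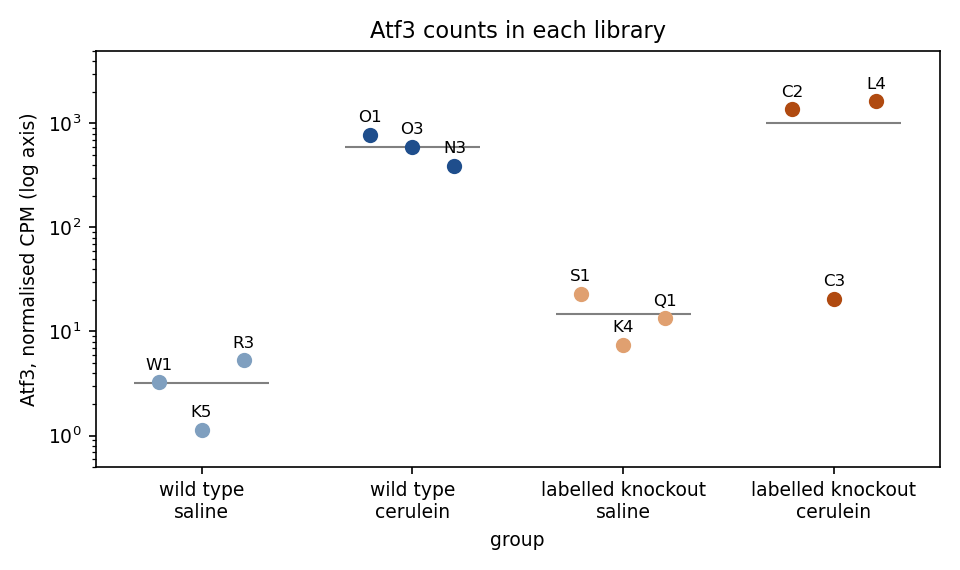
Atf3 level in each library, in CPM on a log axis, by group, with the library codes beside the points and grey lines at the group means. Cerulein libraries lie between 394 and 1636 CPM in both genotypes except C3 at 20.7 CPM, and saline libraries between 1.13 and 23.1 CPM.

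Cerulein separated the libraries more than the genotype label did. The first principal component held 56.3% of the variance and the second 17.7%. On the first, saline libraries lay between -58.8 and -46.4, with overlapping genotype ranges. Cerulein libraries lay between 61.9 and 86.05, except C3 at -55.9. A score that is 0 at the wild-type saline mean and 1 at the wild-type cerulein mean used genes of the wild-type response. It therefore separates the wild-type groups by construction. On it the 6 saline libraries lay between -0.0364 and 0.0844 and the wild-type cerulein libraries between 0.938 and 1.06. C2 scored 0.893 and L4 0.963, but C3, labelled knockout and cerulein, scored 0.0202, inside the saline range. C3 is kept as labelled in all results from 12 libraries, and values without it are given beside edgeR's counts of genes. Markers of other cell types also set libraries apart. Adipoq, the fat-cell hormone adiponectin, stood at 75.0 CPM in N3 and 73.6 CPM in K4, and the immunoglobulin light chain Igkc at 245 and 97.4 CPM. W1 was next in both, at 21.05 CPM of Adipoq and 82.4 CPM of Igkc, so K4 was only slightly above it in Igkc. The insulin gene Ins2 stood at 7596 CPM in L4.

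**Figure D2:**
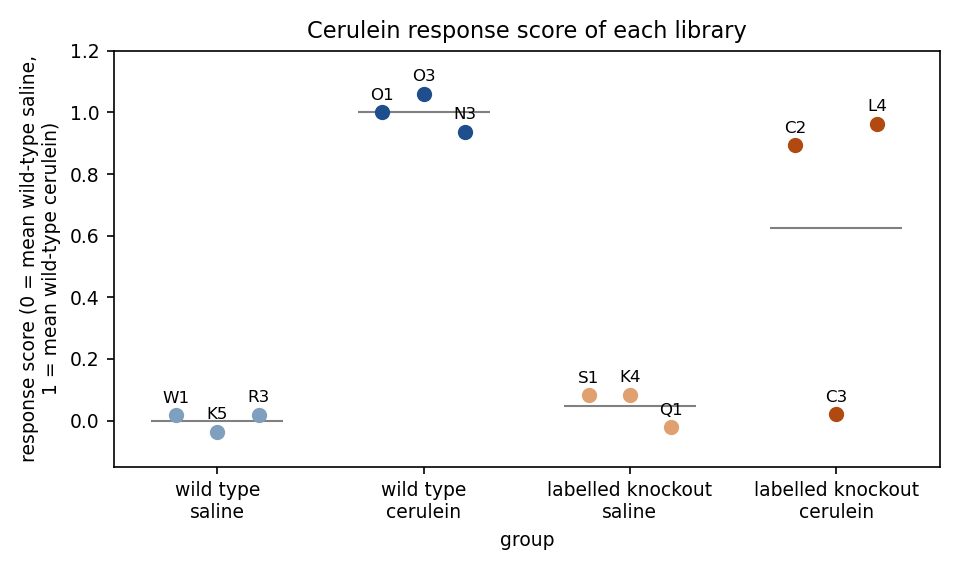
Cerulein response score of each library by group, where 0 is the mean of the wild-type saline libraries and 1 that of the wild-type cerulein libraries, with grey lines at the group means. C3 lies at 0.0202 among the saline libraries, while C2 and L4 lie at 0.893 and 0.963.

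The wild-type comparison asked which genes differ in control pancreas 4 h into cerulein treatment. The cytokine gene Lif (leukaemia inhibitory factor) rose by 9.74 ± 1.67 on the log2 scale (SE, n = 3 per group), from a mean of 0.679 to 571 CPM, and Tac1, the precursor of substance P, by 10.14 ± 2.00, from 0.130 to 155 CPM. Rcan1, a regulator of calcineurin, rose by 7.62 ± 1.44 from 11.9 to 2352 CPM, and Arc, an activity-regulated immediate early gene, by 7.85 ± 1.66. Sephs2, needed for selenoprotein synthesis, changed by -4.43 ± 1.02, Klf15, a metabolic transcription factor, by -4.51 ± 0.82, and the mitochondrial carrier Slc25a34 by -5.33 ± 0.78. Adjusted p was 0.00918 for Lif, Tac1, Rcan1, Klf15 and Slc25a34, 0.0103 for Arc and 0.0118 for Sephs2. For each single gene named as having risen or fallen in wild type, all 3 cerulein libraries lay on the same side of all 3 saline libraries. Chance gives this in 10% of genes. For the largest rises and falls it was a condition of being named, so it is no further support. Counts of list members that rose or fell rest on adjusted p alone. By limma-voom the calls of Lif (adjusted p = 0.0585), Tac1 (0.253) and Arc (0.0877) did not pass, nor did those of Sprr1a (0.0633), Prss56 (0.0568), Reg3g (0.0518) and Dbp (0.0833). With no filter on low counts 23 of 88 named wild-type calls were lost, and by limma-voom 22. The genes named here that lost theirs with no filter were Prss56, Ivl, Reg3g, Cyp4f15, Upp2, Dbp, Hif3a, Amy2a5, Cckar, Reg3b, Reg3d, Sele, Ptgs2, Ccl2, Ccr2, Kdr, mt-Co3 and Hist1h1c, with adjusted p from 0.0531 (Cckar) to 0.136 (Reg3g).

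Further genes with the largest rises were nearly silent in saline. Kel, the Kell blood-group protease, rose by 9.96 ± 1.95, though its locus overlaps another gene model on the same strand and its call did not pass by limma-voom (adjusted p = 0.301). Sprr1a, a cornified-envelope gene, had 1 count in saline and 1665 in cerulein, a 1320-fold ratio with a counting interval of 237 to 52200. S100g, a calcium-binding protein, had 1 and 344 counts, a 273-fold ratio (48.6 to 10800), and it overlaps Ctps2 on the opposite strand. Prss56, a serine protease, and Ivl (involucrin) had 0 counts in saline and were at least 130-fold and at least 106-fold higher in cerulein. Prss56 lost its call without W1, K5, R3, O1 or O3, and Ivl without W1, K5, R3 or O3, with adjusted p reaching 0.062 and 0.0627.

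The genes with the largest falls included metabolic and secreted products. Reg3g, an antimicrobial lectin, changed by -6.34 ± 2.09 (adjusted p = 0.0415), and Sostdc1, a secreted BMP antagonist, by -6.31 ± 1.46 (adjusted p = 0.012). Upp2, a uridine phosphorylase, changed by -5.25 ± 1.55, Cyp4f15, a cytochrome P450, by -5.34 ± 1.45, Hif3a, a hypoxia-inducible factor, by -4.33 ± 1.11, and the circadian factor Dbp, which overlaps Sphk2 on the opposite strand, by -4.68 ± 1.29. Leaving out a single wild-type library, with C3 kept in the fit, could end each of these calls. Reg3g and Upp2 lost theirs whichever of the 6 wild-type libraries was left out (adjusted p up to 0.123 and 0.0925). Without C3 both kept theirs (0.00583 and 8.69e-05), as did the other named genes past the threshold in wild type. Adjusted p was then 4.31e-06 for Sostdc1, 2.5e-05 for Hif3a and 0.000122 for Cyp4f15. C3 is not a wild-type library, but all libraries share 1 estimate of the spread. The coefficient of variation was 0.357 with C3 and 0.304 without it. Dbp lost its call without K5, R3, O1 or O3 (up to 0.0773), Cyp4f15 without R3, O1 or O3 (up to 0.0689), Hif3a without O1 or O3 (up to 0.0624), and Sostdc1 without O3 (0.0509).

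**Figure D3:**
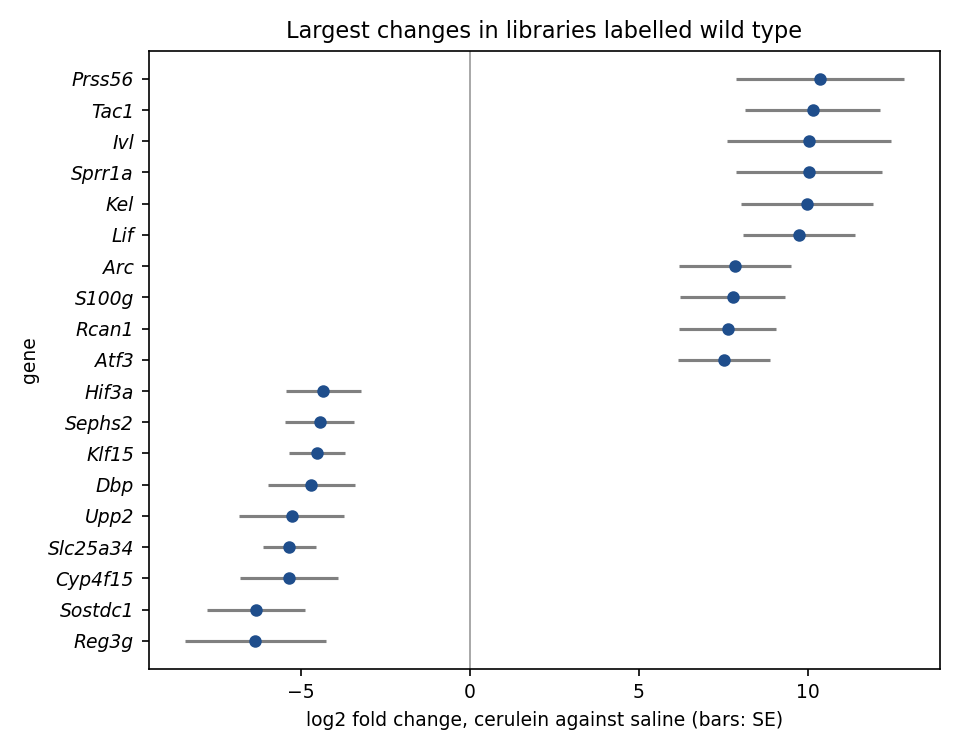
Log2 fold change, cerulein against saline in wild type, of the 10 named genes with the largest rises and 9 with the largest falls, with bars of 1 standard error (n = 3 libraries per group). Values run from 10.35 for Prss56 to -6.34 for Reg3g, and fitted values of genes with 0 or 1 counts in saline depend on the prior count.

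Among early signalling genes, 22 of 28 immediate early genes rose, 1 fell and 5 did not pass (23 higher and 1 lower adjusted over the list alone), with a median change of 2.68. Egr1 rose by 7.36 ± 1.48, Dusp5 by 6.15 ± 1.35 and Fos by 5.48 ± 1.21. Camera gave an adjusted p of 2.52e-09 for the list, and adjusted p = 0.574 with an estimated correlation. By limma-voom Dusp5 (0.0549) and Fos (0.0721) did not pass. Of 21 actin and SRF genes 17 rose, 1 fell and 3 did not pass (17 higher and 1 lower adjusted over the list alone), with a median of 2.54 (camera adjusted p = 1.22e-08, adjusted p = 0.574 with an estimated correlation). Cytoplasmic gamma-actin, Actg1, rose by 5.24 ± 0.94 and the focal-adhesion gene Zyx by 3.46 ± 0.69.

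Integrated stress response and heat shock genes mostly rose, NRF2 targets rose in part, and ER chaperone genes fell more often than they rose. Of 22 integrated stress response genes 18 rose, 1 fell and 3 did not pass (18 higher and 1 lower adjusted over the list alone), including Chac1, which degrades glutathione (7.16 ± 1.47), Sesn2 (5.05 ± 1.11) and the kinase regulator Trib3 (4.40 ± 1.02, not past by limma-voom with an adjusted p of 0.0592). The median was 1.97 (camera adjusted p = 9.48e-08, adjusted p = 0.574 with an estimated correlation). Heat shock genes rose in 10 of 13 cases and 3 did not pass (12 higher and 0 lower adjusted over the list alone), with Hspa1a, an inducible Hsp70, at 6.28 ± 1.07 and a median of 1.30 (camera adjusted p = 1.41e-07, adjusted p = 0.574 with an estimated correlation). Of 13 NRF2 targets 5 rose, 1 fell and 7 did not pass (5 higher and 2 lower adjusted over the list alone). Gclc, the rate-limiting enzyme of glutathione synthesis, rose by 5.04 ± 0.95 and the cystine transporter Slc7a11 by 4.88 ± 1.06. The NRF2 list passed camera (median 1.13, adjusted p = 0.0423, adjusted p = 0.578 with an estimated correlation) but not without K5 (0.079) or N3 (0.0687). Of 25 ER chaperone and degradation genes 2 rose, 7 fell and 16 did not pass (2 higher and 10 lower adjusted over the list alone), with a median of -0.57 (camera adjusted p = 0.00654, adjusted p = 0.574 with an estimated correlation). Sel1l, a subunit of the ER degradation complex, changed by -3.31 ± 0.70, and the co-chaperone Dnajb9 rose by 1.22 ± 0.26.

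Acinar products and identity genes moved down in part. Of 30 digestive enzymes and secretory proteins 2 rose, 10 fell and 18 did not pass (2 higher and 10 lower adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.00404, adjusted p = 0.599 with an estimated correlation). Prss1 (4.24 ± 0.57) and Prss3 (2.26 ± 0.54) rose, but trypsinogen genes are close paralogs whose reads can be shared. The amylase gene Amy2a5 changed by -1.59 ± 0.55 and the protease Ctrc by -1.74 ± 0.48. Amy2a5 lost its call without W1, K5, R3, O1 or N3, and Ctrc without any of the 6 wild-type libraries (adjusted p up to 0.125 and 0.0691). Of 14 acinar identity genes 1 rose, 5 fell and 8 did not pass (2 higher and 5 lower adjusted over the list alone), with a median of -0.57. Camera gave an adjusted p of 0.047 (adjusted p = 0.599 with an estimated correlation), lost without W1 (0.0516), without N3 (0.236), with DESeq2 size factors (0.0521), scaled without the 50 most abundant genes (0.0538) and with a stricter filter (0.0535). Cckar, the cholecystokinin receptor that cerulein binds, changed by -4.17 ± 1.04, a call lost without O1 (0.0524) or O3 (0.0591). Bhlha15, a secretory-cell transcription factor, changed by -1.65 ± 0.41, a call lost without K5 (0.0549) or O3 (0.0505), and the connexin Gjb2 rose by 3.72 ± 0.74. In the Reg family 3 of 6 fell and 3 did not pass (0 higher and 4 lower adjusted over the list alone), with a median of -3.24 (camera adjusted p = 0.00654, adjusted p = 0.578 with an estimated correlation). Its members Reg3g, Reg3b (-3.91 ± 1.26) and Reg3d (-2.58 ± 0.80) each lost the call without at least 5 of the 6 wild-type libraries (adjusted p up to 0.123, 0.116 and 0.0903).

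Genes of duct cells and of growth metabolism were among those that rose. Of 17 ductal and acinar-to-ductal markers 9 rose, 1 fell and 7 did not pass (9 higher and 1 lower adjusted over the list alone), with a median of 1.23 (camera adjusted p = 0.000412, adjusted p = 0.574 with an estimated correlation). The keratins Krt8 (5.12 ± 0.93) and Krt18 (4.19 ± 0.77) and the ductal transcription factor Sox9 (3.49 ± 0.56) were among them. Ribosome biogenesis genes rose in 18 of 20 cases and 2 did not pass (20 higher adjusted over the list alone), with Nop58, a nucleolar protein, at 2.54 ± 0.48 and a median of 1.09 (camera adjusted p = 2.09e-10, adjusted p = 0.574 with an estimated correlation). In contrast 10 of 15 fatty acid oxidation genes fell and 5 did not pass (0 higher and 12 lower adjusted over the list alone), with a median of -1.03 (camera adjusted p = 1.38e-05, adjusted p = 0.574 with an estimated correlation). The regulator Ppara changed by -3.01 ± 0.80, a call lost without K5, R3, O1 or O3 (adjusted p up to 0.0674) and by limma-voom (0.0599). Of 19 cholesterol biosynthesis genes 7 rose and 12 did not pass (7 higher adjusted over the list alone). They included the squalene epoxidase gene Sqle (2.00 ± 0.39), and the list did not pass camera (adjusted p = 0.088).

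Inflammatory genes moved less uniformly, and the lists of immune-cell markers did not pass camera. Of 30 cytokines, chemokines and NF-kB targets 6 rose and 24 did not pass (1 higher adjusted over the list alone), with a median of 1.81 (camera adjusted p = 0.000137, adjusted p = 0.599 with an estimated correlation). Besides Lif these included the adhesion molecule Sele (3.31 ± 1.07), the prostaglandin enzyme Ptgs2 (3.11 ± 0.99) and the monocyte chemokine Ccl2 (2.86 ± 0.94), which all lost the call without any of the 6 wild-type libraries (adjusted p up to 0.122, 0.103 and 0.127). By limma-voom Sele (0.0862) and Ptgs2 (0.0554) did not pass. None of 7 neutrophil or 9 lymphocyte markers and 1 of 13 macrophage markers passed (0 of each adjusted over the list alone), the last being Ccr2 (2.31 ± 0.76), whose call was lost without any of the 6 wild-type libraries (up to 0.129) and by limma-voom (0.0534). The medians were 1.35, 0.86 and 0.53, and camera gave adjusted p values of 0.427, 0.814 and 0.349. For lymphocytes the median was positive and the camera direction negative. Their mean log2 CPM was -0.03 in O1 and -1.39 in O3, below the 0.76 to 2.12 of wild-type saline, and 3.84 in N3. N3, the wild-type cerulein library rich in Adipoq and Igkc, had the highest mean levels of neutrophil, macrophage and lymphocyte markers of the 12 libraries.

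The remaining lists showed few changes. No member of the islet (16), fibroblast (12), adipocyte (10), erythroid (5) or sex-linked (5) lists passed in either adjustment, with medians of 0.39, -0.15, 0.16, -1.27 and 0.03 and camera adjusted p values of 0.566, 0.487, 0.179, 0.0908 and 0.814. For adipocytes the median was positive and the camera direction negative. Their mean log2 CPM was -1.07 in O1 and -1.54 in O3, below the 2.89 to 3.64 of wild-type saline, and 5.06 in N3. The vascular receptor Kdr (-0.65 ± 0.21) was the 1 of 11 endothelial genes past the threshold (0 adjusted over the list alone), lost without any of the 6 wild-type libraries (adjusted p up to 0.12), and the list did not pass (median -0.20, adjusted p = 0.531). Of 13 cell cycle genes the replication gene Mcm6 (1.63 ± 0.38) rose (1 adjusted over the list alone, median -0.03, camera adjusted p = 0.814). Of 20 HDAC and chromatin genes 6 rose (6 adjusted over the list alone), including Hdac5 (1.59 ± 0.32), with a median of 0.20 and an adjusted p of 0.125. Nuclear noncoding RNAs rose in 4 of 10 cases (6 adjusted over the list alone, median 1.01), with camera at an adjusted p of 0.0423 (adjusted p = 0.578 with an estimated correlation), lost without K5 (0.0602) or C3 (0.133) and with a stricter filter (0.0535). Of 12 mitochondrially encoded mRNAs mt-Co3 (-1.65 ± 0.55) passed (0 adjusted over the list alone), a call lost without W1, O1, O3 or N3 (up to 0.258) and by limma-voom (0.118). That list passed camera (median -0.54, adjusted p = 0.0223, adjusted p = 0.599 with an estimated correlation), lost without W1 (0.0989). Of 7 histone genes Hist1h1c (-2.98 ± 0.92) fell (0 adjusted over the list alone), a call lost without any of the 6 wild-type libraries (up to 0.0916), and the list did not pass (median -0.26, adjusted p = 0.245).

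**Figure D4:**
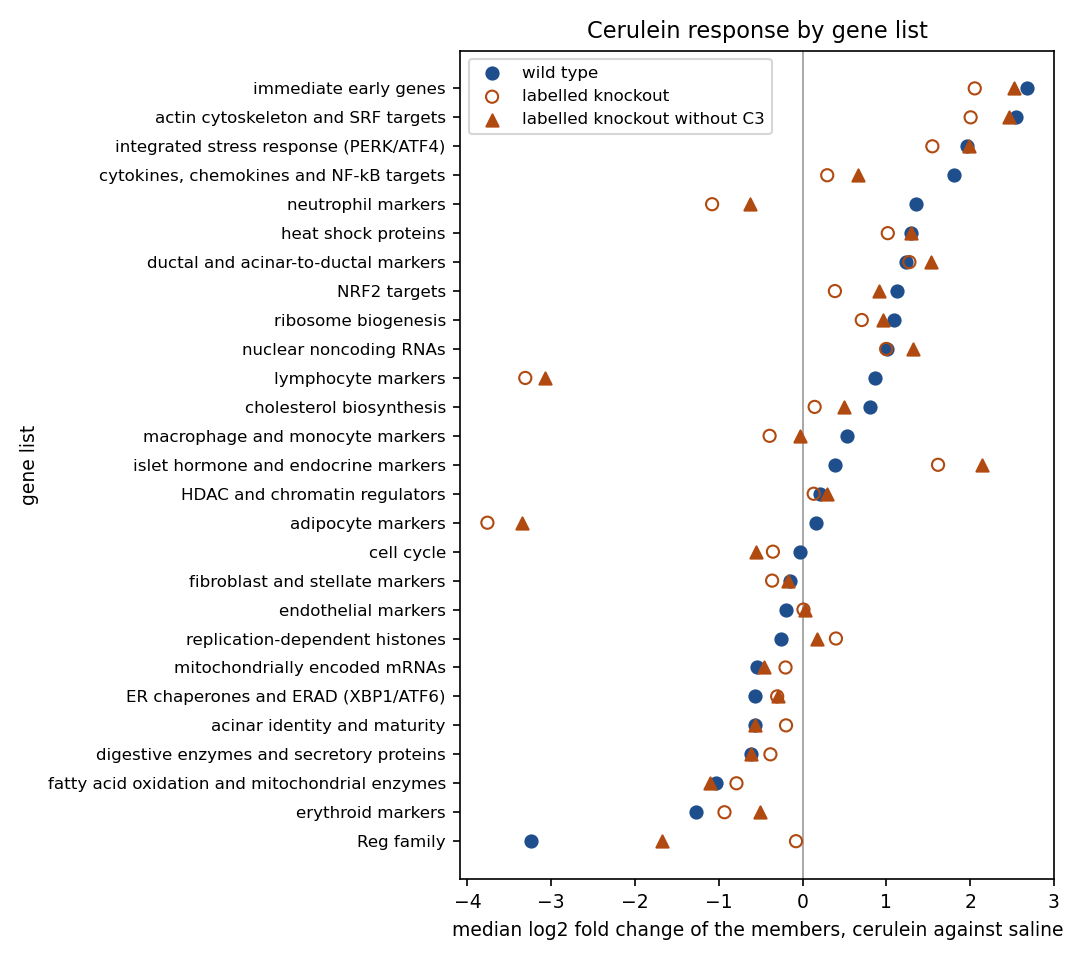
Median log2 fold change of each list's members, cerulein against saline, in wild type (filled circles), labelled knockout (open circles) and labelled knockout without C3 (triangles), for 27 lists. Immediate early genes lie highest in wild type at 2.68 and the Reg family lowest at -3.24.

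In all, edgeR's quasi-likelihood test placed 4399 of 14329 genes past the threshold in wild type, 2568 higher and 1831 lower, and 16 of 29 lists passed camera. Single libraries moved the count by over 1.5 times: it was 2581 without W1, 2205 without K5, 2133 without R3, 2407 without O1 and 1841 without O3. Without C3, which is not a wild-type library, it was 5583 of 14733. The named gene calls lost without a wild-type library were lost in fits that kept C3. With an estimated correlation 0 of 29 lists passed.

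The same comparison in the labelled knockout asked how the line without Atf3, by its label, responds, although Atf3 counts were present in it. Without C3, whose score lay among the saline libraries, Lif rose by 8.55 ± 0.42 (SE, 2 cerulein and 3 saline libraries, adjusted p = 1.59e-06), Tac1 by 9.60 ± 1.02 (0.000161), Kel by 11.02 ± 0.57 (1.61e-06), Arc by 8.98 ± 0.92 (0.000131) and Rcan1 by 7.79 ± 0.38 (1.59e-06). Prss56 and the photoreceptor gene Prph2 had 0 counts in saline and were at least 91.1-fold and at least 95-fold higher, and Sprr1a had 2 and 733 counts, a 357-fold ratio with a counting interval of 98.4 to 2950. Sostdc1 changed by -6.14 ± 0.49 (2.06e-05), Upp2 by -5.85 ± 0.68 (0.000235) and Hif3a by -4.43 ± 0.47 (9.3e-05). Reg3g changed by -5.56 ± 1.60 (0.0279), but with C3 kept its value was -0.01 (adjusted p = 0.996) and its direction turned between settings. With C3 kept none of these genes passed by edgeR, while Lif, Tac1, Kel, Arc, Rcan1 and Prss56 passed by DESeq2.

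Gene groups of the labelled knockout without C3 were counted in the same way. The wild-type counts, standard errors and p values given before come from the fit of 12 libraries, where the spread was larger. They are therefore not comparable between the genotypes. In the fit without C3 edgeR called 5583 genes in wild type and 4306 in the labelled knockout. Of 22 integrated stress response genes 20 rose and 2 did not pass (21 higher and 1 lower adjusted over the list alone), among them Chac1 (7.37 ± 0.56) and Sesn2 (5.57 ± 0.29), with a camera adjusted p of 1.53e-17 and adjusted p = 0.127 with an estimated correlation. Immediate early genes rose in 23 of 28 cases and 1 fell (24 higher and 1 lower adjusted over the list alone, adjusted p = 4.27e-16, adjusted p = 0.0663 with an estimated correlation), with Dusp5 at 6.59 ± 0.58. Actin and SRF genes rose in 17 of 21 cases (18 adjusted over the list alone, adjusted p = 8.63e-21, adjusted p = 0.0549 with an estimated correlation), with Actg1 at 5.13 ± 0.30. Of 17 ductal markers 11 rose (14 adjusted over the list alone, adjusted p = 1.12e-08, adjusted p = 0.0937 with an estimated correlation), with the tight-junction gene Cldn4 at 5.62 ± 0.56 and Krt8 at 5.25 ± 0.33. Ribosome biogenesis genes rose in 19 of 20 cases (20 adjusted over the list alone, adjusted p = 1.99e-09, adjusted p = 0.235 with an estimated correlation) and heat shock genes in 11 of 13 (12 adjusted over the list alone, adjusted p = 1.12e-08, adjusted p = 0.0663 with an estimated correlation). Fatty acid oxidation genes fell in 11 of 15 cases (12 adjusted over the list alone, adjusted p = 8.19e-09, adjusted p = 0.0689 with an estimated correlation), with Ppara at -2.92 ± 0.71. Of 13 NRF2 targets 5 rose and 2 fell (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.0022, adjusted p = 0.231 with an estimated correlation). Of 30 digestive enzymes 2 rose and 8 fell (2 higher and 11 lower adjusted over the list alone, adjusted p = 0.000812, adjusted p = 0.711 with an estimated correlation). Of 16 islet genes 6 rose (11 adjusted over the list alone, adjusted p = 0.0483, adjusted p = 0.828 with an estimated correlation), with Ins1 at 2.90 ± 0.85. In the fit of 12 libraries the islet list also passed (adjusted p = 0.0409, adjusted p = 0.746 with an estimated correlation), but without L4 it turned direction (0.0957), and without S1 (0.118) or with a stricter filter (0.0655) it was lost.

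With all 12 libraries edgeR's quasi-likelihood test placed 0 genes past the threshold in the labelled knockout, with 3256 at an unadjusted p under 0.05 and a lowest adjusted p of 0.086. DESeq2 called 1301 (1188 higher and 113 lower) and limma-voom 0. Without C3 edgeR called 4306 of 14733 (2756 higher and 1550 lower), DESeq2 4478 and limma-voom 4286, so 1 library decided this count.

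The cerulein responses of both genotypes ran in the same direction in most genes. Without C3, 2358 genes were higher in both (586 expected if calls were independent), 1377 lower in both (258 expected) and 1 went opposite ways. Of the wild-type calls 99.1% had the same sign in the labelled knockout, and 98.4% with C3 kept. Across genes, which are not independent replicates, Pearson's r between the responses was 0.687 and Spearman's rho 0.665 over 14329 genes, and 0.748 and 0.724 without C3. The response size was -0.371 over 5485 genes, a smaller response in the labelled knockout. Without C3 it was -0.0839 over 7070 genes. The shifts of the 3 single wild-type cerulein libraries had an SD of 0.116 over the 5485 genes, which is not an error of the response size.

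The comparison in saline asked what the genotype label changes without cerulein, and Atf3 counts were not lower in the libraries labelled knockout. Abundant acinar genes lay close together: the lipase Pnlip differed by 0.13 ± 0.24, the protease Ctrb1 by 0.04 ± 0.25 and Reg1 by 0.01 ± 0.58 (SE, n = 3 per group), and none passed. Among lists, macrophage markers were higher as a group (median 0.57, camera adjusted p = 0.000186, adjusted p = 0.955 with an estimated correlation), with Lyz2, lysozyme, at 0.72 ± 0.70 and the mannose receptor Mrc1 at 0.49 ± 0.46. That call was lost without K5 (0.104) or K4 (0.869), and K4 was the saline library with the highest mean level of these markers. Islet genes were lower as a group (median -0.69, adjusted p = 0.00536, adjusted p = 0.955 with an estimated correlation), with Ins2 at -0.87 ± 0.97, lost without S1 (0.101) and turned without K5 (0.565). Fibroblast markers were higher (median 0.26, adjusted p = 0.0426, adjusted p = 0.955 with an estimated correlation), lost without W1 (0.253), K5 (0.157), S1 (0.196) or C3 (0.0521) and turned without K4 (0.869). Ductal markers were lower (median -0.10, adjusted p = 0.0426, adjusted p = 0.955 with an estimated correlation), lost without W1 (0.343), K5 (0.0986), S1 (0.0764) or K4 (0.54). Mitochondrially encoded mRNAs were lower (median -0.10, adjusted p = 0.0273, adjusted p = 0.955 with an estimated correlation), lost without W1 (0.813) or K4 (0.869). With no filter on low counts the ductal (0.139), islet (0.0685), fibroblast (0.139) and mitochondrial (0.143) calls were also lost, and the ductal call with a stricter filter (0.0609). No list member passed over all genes. EdgeR's quasi-likelihood test placed 0 of 14329 genes past the threshold, with 60 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Without C3 edgeR called 0 of 14733, with 132 at an unadjusted p under 0.05.

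The comparison in cerulein asked what the genotype label changes after treatment. The Reg family was higher in the labelled knockout as a group (median 2.80, camera adjusted p = 0.000254, adjusted p = 0.608 with an estimated correlation), with 0 of 6 members past the threshold over all genes and 4 higher adjusted over the list alone, and Reg3b at 3.45 ± 1.23. That call was lost without C3 (0.059), where the median was 0.58 and Reg3b at 2.01 ± 1.16. Cytokines were lower as a group (median -0.86, adjusted p = 4.97e-06, adjusted p = 0.608 with an estimated correlation), with Lif at -1.35 ± 1.14. Ribosome biogenesis (median -0.35, adjusted p = 5.86e-06, adjusted p = 0.608 with an estimated correlation) and heat shock genes (median -0.62, adjusted p = 6.96e-06, adjusted p = 0.608 with an estimated correlation) were also lower, and ER chaperones higher (median 0.31, adjusted p = 0.00317, adjusted p = 0.608 with an estimated correlation). Examples are the nucleolar protein Npm1 at -0.49 ± 0.21, the chaperone Hspa8 at -0.73 ± 0.36 and the ER stress gene Herpud1 at 0.68 ± 0.31, none of them past the threshold. Without C3 Lif was at -0.76 ± 0.33, Npm1 at -0.32 ± 0.18, Hspa8 at -0.37 ± 0.23 and Herpud1 at 0.76 ± 0.34, so most of these differences shrank. Cytokine, ribosome biogenesis, heat shock and ER chaperone calls held without each single library, but without C3 the medians were -0.52, -0.13, -0.27 and 0.14. Lymphocyte markers were lower (median -3.82, adjusted p = 0.000465, adjusted p = 0.608 with an estimated correlation), a call lost without N3 (0.287), the library with the highest Igkc level.

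EdgeR's quasi-likelihood test placed 0 of 14329 genes past the threshold in that comparison, with 1146 at an unadjusted p under 0.05, and limma-voom called 0. Without C3 edgeR called 0 of 14733, with 747 at an unadjusted p under 0.05. DESeq2 called 11 (7 higher and 4 lower), and 14 without C3 (4 higher and 10 lower), with 3 shared. The 3 shared genes, chosen after their values were seen, were the cholesterol transporter Npc1 (-1.76 ± 0.35, adjusted p = 0.0042), the lipase co-activator Abhd5 (-1.02 ± 0.22, adjusted p = 0.0106) and the phosphatase Ptpn4 (-1.17 ± 0.25, adjusted p = 0.0106), each with an edgeR adjusted p of 0.604. Of 29 lists 16 passed camera, 8 without C3 and 0 with an estimated correlation. Without C3 adjusted p was 0.913 for immediate early genes and for ductal markers, 0.676 for digestive enzymes (turned), 0.375 for macrophage markers and for histones, 0.229 for neutrophil markers, 0.203 for actin and SRF targets (turned) and 0.061 for fatty acid oxidation (turned). Without N3 it was 0.824 for macrophage markers, 0.651 for neutrophil markers, 0.424 for histones and 0.287 for digestive enzymes. Without O1 it was 0.179 for histones, 0.107 for ductal markers, 0.0797 for digestive enzymes and 0.0618 for fatty acid oxidation. Without O3 it was 0.201 for ductal and 0.121 for endothelial markers, and without L4 0.435 for endothelial markers, 0.0791 for neutrophil markers and 0.0617 for macrophage markers and for histones. Histones also lost the call with no filter on low counts (0.0795).

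The direct test of whether the cerulein response depends on the genotype label is the difference of the responses. No single gene passed. Reg3b had a difference of 3.77 ± 1.63 (SE) and Cckar of 3.02 ± 1.32, both with an adjusted p of 0.812. Without C3 these were 2.33 ± 1.56 and 0.41 ± 0.60 (adjusted p = 0.999 for each). Atf3 had a difference of -1.40 ± 1.47 (adjusted p = 0.838), and of -0.82 ± 0.78 without C3 (adjusted p = 0.999). As groups, cytokines (median -1.52, camera adjusted p = 9.21e-06, adjusted p = 0.611 with an estimated correlation) and macrophage markers (median -1.16, adjusted p = 0.000158, adjusted p = 0.611 with an estimated correlation) had lower responses in the labelled knockout. Both calls held without each single library (medians -1.09 and -0.79 without C3) and were lost without N3 and K4 together (0.0628 and 0.736), a fit chosen after seeing the data. Ribosome biogenesis (median -0.39) and heat shock genes (median -0.61) had lower responses (adjusted p = 0.000158 for each, adjusted p = 0.611 with an estimated correlation). These calls held without each single library, with medians of -0.18 and -0.26 without C3. Their differences of library means were only -0.44 ± 0.33 and -0.87 ± 0.53 (SE) with 12 libraries. Without C3 they were -0.14 ± 0.18 and -0.35 ± 0.15. The Reg family had a less negative response (median 3.12, and 0.90 without C3, adjusted p = 0.000158, adjusted p = 0.611 with an estimated correlation). Lymphocyte markers had a lower response (median -4.09, adjusted p = 0.0018, adjusted p = 0.611 with an estimated correlation), lost without N3 (0.415), and immediate early genes too (median -0.63, adjusted p = 0.000158, adjusted p = 0.611 with an estimated correlation), lost without C3 (0.402).

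EdgeR's quasi-likelihood test placed 0 of 14329 genes past the threshold for this difference, with 594 at an unadjusted p under 0.05 and a lowest adjusted p of 0.812, and DESeq2 and limma-voom called 0. Without C3 it was 0 of 14733, with 508 at an unadjusted p under 0.05. Of 29 lists 14 passed camera, 8 without C3 and 0 with an estimated correlation. In simulated counts of 12 libraries a 4-fold difference of responses was recovered in 38.5% of genes and a 2-fold difference in 0%, and without C3 in 51% and 0%.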

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

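The tests of C3, of the Atf3 counts and of the immune lists and the regroupings without C3 were chosen only after those results were seen, while the regroupings of all 12 libraries and the count of genes past the threshold near Atf3 were set beforehand.

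C3, labelled knockout and cerulein, lies among the saline libraries. An exchange with a saline library would leave a saline library with a high response score, and 0 of 6 scored above 0.5, which argues against it. No effective cerulein exposure, or a wrong treatment label, would give a score near 0, and C3 scored 0.0202. Loss of Atf3 preventing the response would lower all 3 scores, and the lowest of the others was 0.893. This argues against it only if C2 and L4 lack Atf3, which their levels of 1375 and 1636 CPM leave open. A missing exposure, a wrong treatment label and loss of Atf3 thus stay open, and the labels hold nothing to test them further.

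Atf3 counts are not lower in the libraries labelled knockout. An exchange of genotype labels with an allele that gives no counts would leave 3 cerulein libraries near 0, and the lowest cerulein count apart from C3 was 11124, which argues against it. An allele whose remaining exons are transcribed and counted could respond to cerulein, and the labelled knockout log2 change without C3 was 6.68, but a wild-type allele would give the same value, so mis-genotyping stays open. A passenger interval around Atf3 from another mouse strain might carry genotype differences, but planned tests within 20 Mb had 0 genes past the threshold in saline and 0 in cerulein, so they cannot tell. At unadjusted p, 0 of 4 versions had an adjusted Fisher p under 0.05 (lowest 0.0702), which leaves it undecided.

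Immune and cytokine lists are lower in the difference of cerulein responses. Fat and lymphoid tissue carried with N3 and K4 could produce this, and 0 of 4 lists stayed past the threshold without both libraries, but this stays open. For the neutrophil and macrophage lists the medians went from -2.29 and -1.16 to 0.24 and 0.10 (0 of 2 below 0). Their differences of library means went from -1.59 ± 1.88 and -1.03 ± 0.89 (SE) to 0.25 ± 1.72 and -0.15 ± 0.79. But the adipocyte median went from -3.92 to 5.32, and its difference of library means from 0.24 ± 2.97 to 3.97 ± 1.68. Leaving out both turned that median, not the library means, and did not balance the fat markers between the groups. For cytokines the median only went from -1.52 to -0.84 (library means -1.15 ± 1.39 and -0.42 ± 1.63), and the lymphocyte list decides nothing without N3 and K4, since these were picked by its markers. C3 alone or a smaller inflammatory response in the labelled knockout might also produce it, and neither is decided: without C3, 3 of 4 lists stayed past the threshold at the preset correlation, but library means differed by only -0.52 ± 1.40 (cytokines), -0.74 ± 1.90 (neutrophil), -0.56 ± 0.86 (macrophage) and -1.21 ± 2.00 (lymphocyte), and without N3, K4 and C3 the cytokine adjusted p was 0.678, with a median of -0.50, 23 of 30 members lower and library means differing by 0.20 ± 1.64.

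Camera placed these lists past the threshold in the difference of cerulein responses. Adjusted p was 0.000158 for the Reg family (higher), 0.0247 for ER chaperones (higher), 0.000158 for immediate early genes (lower), 9.21e-06 for cytokines (lower), 0.00558 for neutrophil markers (lower), 0.000158 for macrophage markers (lower) and 0.0018 for lymphocyte markers (lower). It was 0.000158 for ribosome biogenesis (lower) and 0.000158 for heat shock genes (lower), 0.00113 for actin and SRF targets (lower), 0.0224 for fatty acid oxidation (higher), 0.0185 for mitochondrially encoded mRNAs (higher) and 0.0106 for histones (higher). With an estimated correlation the lowest adjusted p was 0.611. Single libraries ended many of these calls: without C3 adjusted p was 0.758 for actin and SRF targets, 0.516 for fatty acid oxidation (turned), 0.516 for mitochondrially encoded mRNAs, 0.402 for immediate early genes, 0.168 for histones, 0.0591 for ER chaperones and 0.0546 for neutrophil markers. Without N3 it was 0.415 for lymphocyte markers, 0.181 for histones and 0.174 for neutrophil markers, and without K4 0.215 for neutrophil markers, 0.184 for mitochondrially encoded mRNAs and 0.119 for ER chaperones. ER chaperones also lost the call without W1 (0.0985), S1 (0.19) or L4 (0.0867), mitochondrially encoded mRNAs without W1 (0.175), histones without O1 (0.0845) and fatty acid oxidation without S1 (0.0831).

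Libraries were also regrouped in every way that mixes the compared labels. In wild type the labelled grouping had 4399 genes past the threshold, 1 of 10 groupings reached this and the highest other had 0. In the labelled knockout the labelled grouping had 0, 10 of 10 reached it and the highest other had 787, with S1, Q1 and C3 against K4, C2 and L4, which follows the response scores (0.0827, -0.0211 and 0.0202 against 0.0844, 0.893 and 0.963) apart from K4, the saline library rich in Adipoq. In saline the value was 0, 10 of 10 reached it and the highest other was 0, and in cerulein it was 0, 10 of 10 and 0. With 10 groupings no share under 0.05 is possible, and a value of 0 is reached by any grouping. For the difference of responses, 100 of 200 regroupings were drawn: the value was 0, 100 of 100 reached it and the highest other was 1, and without C3 it was 0, 100 of 100 and 202, in a drawn regrouping whose libraries were not examined, so what it follows is open. The response size of 0.371 was reached by 18 of 100 with a highest other of 0.454, and without C3 that of 0.0839 by 31 of 100 with a highest other of 0.185, so chance is not excluded.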

How the results depend on the processing

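The fits without C3 for the wild-type and saline comparisons, the fits without N3 and K4, without N3, K4 and C3, and with Y-linked libraries only, and DESeq2 and limma-voom without C3, were chosen only after the results were seen. In simulations with 200 changed genes at most 0.5% of 2-fold changes were recovered with 12 libraries and 2.5% without C3. These shares do not apply to the wild-type response, where 4399 genes passed and the adjustment is less strict. No sex or batch is stated, and no paired analysis was possible because no replicate codes are shared across groups. The labelled knockout count, the response size and many list calls changed without C3. Neutrophil and macrophage calls were lost in the difference of responses without N3 and K4 together, and in cerulein without N3. In cerulein they were also lost without C3 (camera adjusted p = 0.229 and 0.375) or L4 (0.0791 and 0.0617). Whether tissue carried with N3 and K4 is the cause stays open. For other changes the cause was not tested. With an estimated correlation 0 wild-type lists passed. With no filter on low counts 23 of 88 named wild-type calls were lost, by limma-voom 22 and by DESeq2 4. With the wild-type groups fitted alone 87 kept their call. Whichever single wild-type library or C3 was left out, 51 kept it. Every such loss came with a wild-type library left out and C3 kept, and none with C3 left out.

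By DESeq2 the labelled knockout response had 1301 genes and the cerulein comparison 11, with Reg3g in the labelled knockout at 0.0375. Reg3g was 0.0364 with DESeq2 size factors, 0.000518 when scaled without the 50 most abundant genes and 0.0755 with no filter on low counts, against -0.01 in the 12-library fit. By limma-voom Atf3 in cerulein was -0.726. By DESeq2 without C3 the labelled knockout had 4478 genes, the cerulein comparison 14 and the response size was -0.0865. By limma-voom without C3 the labelled knockout had 4286.

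Without N3 and K4 the response size was -0.491, and adjusted p was 0.895 for fibroblast markers in saline, 0.672 for neutrophil markers and 0.222 for lymphocyte markers in the difference of responses. All 3 turned direction.

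Without N3, K4 and C3 the labelled knockout had 4319 genes and the response size was -0.137. Adjusted p in saline was 0.86 for fibroblast markers. In cerulein it was 0.226 for digestive enzymes, 0.624 for neutrophil, 0.136 for macrophage and 0.999 for lymphocyte markers, 0.642 for actin and SRF targets, 0.237 for fatty acid oxidation and 0.815 for histones. In the difference of responses it was 0.218 for neutrophil, 0.25 for macrophage and 0.119 for lymphocyte markers, 0.934 for actin and SRF targets, 0.615 for fatty acid oxidation, 0.79 for mitochondrially encoded mRNAs and 0.988 for histones. Each of these lists turned direction.

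With Y-linked libraries only the labelled knockout had 3297 genes and the response size was -0.0759. Adjusted p in cerulein was 0.769 for digestive enzymes, 0.199 for actin and SRF targets and 0.0518 for fatty acid oxidation, and 0.154 for fatty acid oxidation in the difference of responses, each with the direction turned.

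With each library left out in turn, the wild-type count ran from 1841 (O3) to 5583 (C3), the labelled knockout count from 0 (S1) to 4306 (C3) and the response size from -0.549 (C2) to -0.0839 (C3). Adjusted p in saline ran from 4.79e-08 (W1) to 0.565 (K5, turned) for islet markers and from 2.37e-05 (Q1) to 0.869 (K4, turned) for fibroblast markers. In cerulein it ran from 0.000934 (L4) to 0.676 (C3, turned) for digestive enzymes, from 7.11e-05 (L4) to 0.203 (C3, turned) for actin and SRF targets, and from 7.11e-05 (L4) to 0.0618 (O1) for fatty acid oxidation, with 0.061 and a turned direction without C3. In the difference of responses fatty acid oxidation ran from 0.000106 (L4) to 0.516 (C3, turned), and islet markers in the labelled knockout from 6.22e-05 (C2) to 0.118 (S1), with 0.0957 and a turned direction without L4. Labelled knockout log2 changes ran from -5.56 (C3) to 1.80 (S1) for Reg3g, -5.34 (C3) to 0.10 (L4) for Fam13a, -0.10 (L4) to 3.09 (C3) for Chgb, -0.13 (L4) to 2.90 (C3) for Ins1, -0.25 (L4) to 2.77 (C3) for Ins2, -0.20 (L4) to 4.08 (C3) for Dusp4 and -2.44 (C3) to 0.40 (S1) for Hist1h1c.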

Other observations

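Everything in this part was tested only after the values were seen.

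A stretch of chromosome 6 from 40948375 to 41704339 (GRCm38) holds the trypsinogen genes, T-cell receptor beta segments, Trpv6 and Kel. Of 27 genes tested there in wild type, 17 were higher in cerulein and 0 lower, against 2568 higher and 1831 lower among all 14329 genes. Among the 17 were T-cell receptor J segments with 1 or 2 counts in saline and at most 0.663 CPM in cerulein. Trypsinogen-like 1810009J06Rik went from 1.92 to 1242 CPM (9.31 ± 1.79 on the log2 scale), Prss1 rose by 4.24 ± 0.57, the calcium channel Trpv6 by 4.61 ± 1.02 and the receptor constant segment Trbc1 by 3.72 ± 0.80. The abundant Prss2 stayed at -0.40 ± 0.21, from 52910 to 40230 CPM. The trypsinogen genes are close paralogs, so which of them rose is uncertain. Transcription running past abundant genes could raise silent neighbours on the same strand. Prss2 and Trbc1 lie on the plus strand, but Trpv6 and Kel on the minus strand. Running past Prss2 thus cannot account for Trpv6 and Kel if the counting kept strands, and its strand setting is not given. Transcription past abundant genes was examined in 9 settings (3 numbers of abundant genes by 3 distances) with and without the stretch. In 0 of 9 settings was the adjusted p under 0.05 with the stretch left out, and 0 of 9 with it kept, with Fisher p from 0.183 to 0.938 and from 0.0706 to 0.883, so these tests cannot tell.

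Sex-linked counts differ between libraries of the same group. Xist, made from the inactive X chromosome, stood at 138 CPM in W1 and 205 CPM in S1, with 0 counts of 4 Y-linked genes. C3 had 16 Xist counts (0.681 CPM) and 0 Y-linked counts, so it has neither mark. The other 9 libraries had 841 to 1932 Y-linked counts. W1 and S1 are both saline libraries, and no cerulein library has a comparable Xist level, so this pattern is not balanced between treatments. The labels do not state the sex. In fits of the Y-linked libraries alone the wild-type count was 4545 and the labelled knockout count 3297, and the response size was -0.0759.

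Islet genes stand out in L4, labelled knockout and cerulein, where Ins2 reached 7596 CPM. Without C3 the labelled knockout rise of Ins2 was 2.77 ± 0.85 (adjusted p = 0.0352), while without L4 and with C3 kept it was -0.25. A larger share of islet tissue in L4 may explain it, but leaving out L4 cannot decide this. L4 was picked for its islet genes, and without it the labelled knockout cerulein group holds only C2 and C3. Their Ins2 levels were 688.6 and 197.5 CPM. In that fit the islet list had a camera adjusted p of 0.0957, with the direction turned.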
